A study of Mus musculus with 2 samples.

How the data were processed

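RNA from nuclei was sequenced in 2 pooled libraries, 1 from wild-type mice and 1 from Kmt2d +/mut mice. Per the labels' protocols, mice aged 8 weeks received 150 mg/kg of EdU by intraperitoneal injection, and the dentate gyrus was dissected after 16 h. EdU is a thymidine analogue that is built into DNA during S phase. Nuclei that carried it were stained by click chemistry and sorted, and 500 nuclei per genotype were pooled from 3 mice. Libraries followed a modified Smart-seq2 protocol, which amplifies full-length cDNA from polyadenylated RNA, with 22 cycles of cDNA amplification and 20 cycles of enrichment after tagmentation, per the labels' protocols. The labels describe no molecular identifiers and no strand marking, so PCR copies cannot be told from separate molecules, and overlapping or antisense genes can share reads.

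The submitters' processing notes name HISAT2, Cuffnorm and Cuffdiff and the mouse build mm10. Their versions, the annotation and the settings are not given in the sources used here. The values used were the gene-level FPKM (fragments scaled to transcript length and to library size) that the authors deposited in a table in the layout of Cuffdiff. The same table holds the p-value and q-value of the authors' own test for each gene and pair of libraries, a test status and a call, all copied as deposited. It lists all pairs of 6 libraries. The pair named for Kabuki syndrome type 1 mutant and wild-type EdU nuclei was matched to the 2 samples by its names, and the other 4 libraries were not used. The authors gave their fold as wild-type over mutant, and every ratio here is Kmt2d +/mut over wild-type. In the 3198 entries above 0 in both libraries, the deposited log2 fold differed from that of the deposited values by at most 5.2e-05. In 2254 entries of this pair the deposited fold held text in place of a number, and it was not used there.

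The pair had 24346 entries. Of these, 27 had a date in place of a gene name and were left out of all counts and lists, and the other 24319 symbols each had 1 entry. Coordinates, gene types and transcript lengths came from the GENCODE annotation of the same build, in which 96.3% of the symbols with a value above 0 in either library were found by name. Genes sharing sequence with pseudogenes or paralogs, as many ribosomal protein and glycolysis genes do, are uncertain, since it is not stated how reads fitting several places were handled.

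With 1 library per genotype no test between genotypes was made here, and no p-value or SD between libraries was computed. The measure was log2((Kmt2d +/mut FPKM + 1)/(wild-type FPKM + 1)), with a pseudocount of 1, over genes with an FPKM of 1 or more in at least 1 library. This scale understates the differences of genes with low values. For a gene listed at 0 in 1 library it is set by the level in the other library and the pseudocount, and no fold is given for such genes. An exact 0 in such a table can also be a failed estimate, so these genes are described as listed at 0. Of 23 gene lists, 22 had members over this minimum. Each list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins (seed 1). A percentile under 2.5 or over 97.5 was called apart. This describes these libraries and is not a test between genotypes. The lists, the measure, the rule for named genes and all alternatives but 1 were chosen before the data were examined.

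The rule named Kmt2d, then the 10 genes with the largest and the 10 with the smallest ratio among genes called in the authors' deposited table with an FPKM of 1 or more in both libraries. That part gave 0 genes. The rule's fallback, which was written for a table without calls, was used in its place, and takes the same from genes with an FPKM of 5 or more in both libraries. The rule also named the 5 genes with the highest FPKM among those listed at 0 in the other library, for each library, passing over small RNAs and unnamed gene models. From each list it named the 4 members with the highest mean FPKM and any member called in the authors' deposited table. A few genes that the rule names are not reported here.

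Sequencing depth was estimated from the steps between low FPKM values, as no total count was used here. In genes with 1 annotated transcript longer than 800 bp, a step and an amount taken off the length were fitted per library (190 bp in wild-type, 170 bp in Kmt2d +/mut). With these, 82.1% of 84 low values in the wild-type library and 79.7% of 69 in the Kmt2d +/mut library lay within 0.1 of a whole number of fragments. With their mean of 180 bp in both, 1 fragment was worth 4.57 FPKM on a shortened length of 1 kb in the wild-type library and 4.60 in the Kmt2d +/mut library. That is about 219000 and 217000 fragments, if the FPKM of each library was scaled by its own total. The sources used here do not state this scaling. Both values were medians within the same narrow window, and the steps were searched over a limited range, so similar depths were partly built in. In single-transcript genes above 0, the median estimate was 16.8 fragments in the wild-type library and 16.3 in the Kmt2d +/mut library. Intervals from such estimates cover counting error only. They leave out the error of the estimate itself, the amplification and the difference between mice.

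Alternatives were a pseudocount of 0.1, no minimum, a minimum of 5, ratios centred on the median of genes with an FPKM of 5 or more in both libraries, only genes that the authors tested, the authors' own fold, symbols with 1 entry, and, for the authors' calls, a q-value under 0.01 or an FPKM of 1 or more in both libraries. Restricting all ratios to genes above 0 in both libraries was added after the data were examined. The placing of lists was tested on simulated shifts added to the real ratios of 7903 genes, shuffled across genes, with 60 lists for each size and shift. Shuffling breaks the tie between ratio and expression level, and fewer random lists were drawn than in the real placing. The rates that follow are therefore only a rough guide to it. Lists of 30 genes were called apart in 5% of cases with no shift, in 41.7% with a log2 shift of 2 and in 95% with a shift of 4. Lists of 10 genes were called in 6.67%, 18.3% and 63.3% of cases, and lists of 70 genes in 3.33%, 86.7% and 100%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.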

Results

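The series measured gene expression in dividing cells of the adult mouse dentate gyrus, a part of the hippocampus where neural stem cells go on making granule neurons. Mice were wild-type or carried 1 mutant allele of Kmt2d (Kmt2d +/mut). KMT2D is a histone methyltransferase acting on lysine 4 of histone H3 (H3K4), and loss of 1 copy in people causes Kabuki syndrome type 1. For each genotype, 500 nuclei labelled by EdU within the 16 h before sampling were pooled from 3 mice into 1 RNA-seq library. There were no replicate libraries, so no difference below has a replicate check. FPKM was above 0 for 5787 genes in the wild-type library and for 5443 in the Kmt2d +/mut library, with medians of 26.9 and 29.4 among those genes. The FPKM of all genes summed to 442190 and 390074, and the 10 most abundant genes held 7.19% and 6.92% of the sum. Depth, estimated from the steps between low values, was about 219000 fragments in the wild-type library and 217000 in the Kmt2d +/mut library. This holds only if FPKM was scaled by each library's own total.

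The comparison of genotypes asks how the loss of 1 intact Kmt2d allele alters expression in these cells. Kmt2d itself (mm10, chromosome 15, 98831669 to 98871204, minus strand) was read at 34.7 FPKM in wild-type and 23.5 in Kmt2d +/mut nuclei, 67.8% of the wild-type level. Among the other genes of the H3K4 methylation machinery, Ash2l and Rbbp5, core subunits shared by the KMT2 complexes, stood at 59.0 and 92.1 FPKM in wild-type and were listed at 0 in Kmt2d +/mut, and the authors' deposited table calls both lower. Kmt2c, the closest relative of Kmt2d, had similar values of 62.7 FPKM in wild-type and 55.3 in Kmt2d +/mut. Dpy30, another shared subunit, stood at 9.04 in wild-type and 211 in Kmt2d +/mut, and the H3K4 demethylase Kdm1a at 14.4 and 241, with no call for either in the authors' deposited table. Of 21 genes of this list over the minimum, 14 were above 0 in both libraries, of which 4 were at least 2-fold higher in Kmt2d +/mut, 5 at least 2-fold lower and 5 within 2-fold. The list's median log2 ratio of -1.14 lay at percentile 25.5 of matched random lists, and over the 6 members the authors tested it was 1.89, in the opposite direction. For Kmt2d, the exact binomial 95% interval of the ratio of estimated fragments, 149 in wild-type and 100.3 in Kmt2d +/mut, ran from 0.519 to 0.877 and covers counting error only. The authors' deposited table did not test Kmt2d. If the mutant allele is a gene trap, it can keep the part of the transcript before its insertion. Of 3182 genes above 0 in both libraries only 1206 were within 2-fold, so the Kmt2d value does not check the labels.

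Genes with very different readings in the 2 libraries ran in both directions. The authors' deposited table calls 415 named genes higher and 463 lower in Kmt2d +/mut. Every one of these 878 genes was listed at 0 in 1 of the libraries. The largest values listed at 0 in Kmt2d +/mut belonged to Pomp, a proteasome assembly factor, at 998 FPKM in wild-type, Ergic3, which cycles between the endoplasmic reticulum and Golgi, at 970.3, and the proteasome subunit Psmb2 at 934. Lamtor2, part of the lysosomal Ragulator complex, and Ccnc, the cyclin of the Mediator kinase module, followed at 863 and 797 FPKM, and the authors' deposited table calls all 5 of these genes lower with q-values from 0.00308 to 0.029. Listed at 0 in wild-type were Ndufa3 at 854 FPKM in Kmt2d +/mut, Cnpy2 at 732, Romo1 at 704, Atp5j2 at 689.5 and Cox6c at 599. Of these, Cnpy2, Atp5j2 and Cox6c are called higher in the authors' deposited table with q-values of 0.00308, 0.029 and 0.029, while Ndufa3 and Romo1 are not called, at q-values of 0.175 and 0.369. Small RNAs were passed over in this ranking.

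Over 7903 genes with an FPKM of 1 or more in at least 1 library, 3198 were at least 2-fold higher and 3499 at least 2-fold lower in Kmt2d +/mut. Of all these genes, 2197 were listed at 0 in wild-type and 2524 in Kmt2d +/mut, together 59.7%. Among the 3182 genes above 0 in both libraries, 1001 were at least 2-fold higher, 975 at least 2-fold lower and 1206 within 2-fold. In the authors' deposited table, 3249 named genes were tested, each with an FPKM of at least 49.85 in 1 of the libraries. Of these, 1423 were listed at 0 in 1 library, and the authors' deposited table calls 61.7% of them. The other 1826 were above 0 in both libraries, and the authors' deposited table calls 0 of them, with a smallest q-value of 0.178 and 2 genes with an unadjusted p-value under 0.05.

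**Figure D1:**
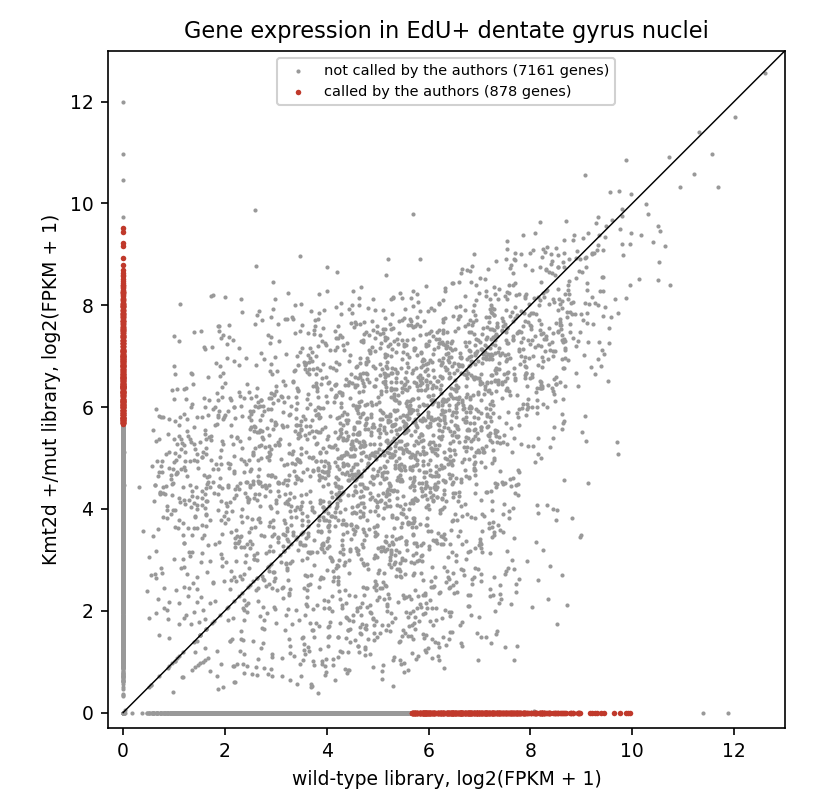
Each point is a gene, with log2(FPKM + 1) in the wild-type library on the horizontal axis and in the Kmt2d +/mut library on the vertical axis, and the line marks equal values. The 878 genes called in the authors' deposited table (red) all lie on an axis, where the FPKM is listed at 0 in 1 library.

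Among genes with an FPKM of 5 or more in both libraries, Slc25a4, the mitochondrial exchanger of ADP and ATP, had the largest ratio, at 938 FPKM in Kmt2d +/mut and 5.005 in wild-type. Sdccag3 stood at 439 and 5.09, the tetraspanin Tspan31 at 348 and 6.74, the lysosomal membrane protein gene Glmp at 501 and 10.2, and the sorting nexin Snx6 at 235 and 5.39. Psip1, a chromatin-binding protein on the H3K4 list, stood at 279 FPKM in Kmt2d +/mut and 6.87 in wild-type. At the other end, the proteasome subunit Psmb6 was read at 391 FPKM in wild-type and 5.50 in Kmt2d +/mut. The respiratory chain subunit Cox4i1 stood at 505 and 9.85, the ATP synthase subunit Atp5f1 at 333 and 6.36, the prolyl isomerase Fkbp1a at 506 and 10.2, Angel2 at 282 and 5.08, and the pro-apoptotic gene Bax at 245 and 6.88. None of the 20 genes with the most extreme ratios in this group is called in the authors' deposited table, and the q-value for Slc25a4 there is 0.565. In the library where they were lower, several of the 20 genes stood close to the minimum of 5 FPKM. There 1 fragment is worth an estimated 4.57 FPKM in wild-type or 4.60 in Kmt2d +/mut on a shortened length of 1 kb. Their ratios can therefore rest on few fragments. Over the 2377 genes with an FPKM of 5 or more in both libraries the median log2 ratio was 0.02. The log2 values of the libraries correlated across genes with a Pearson r of 0.454 and a Spearman rho of 0.412, and genes are not independent replicates.

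Markers of the stages from stem cell to granule neuron were read only in part. None of these lists was called apart, which at such list sizes does not exclude a shift. Listed at 0 in both libraries were 10 of 28 stem cell, 4 of 18 progenitor, 6 of 25 immature and 6 of 27 mature markers. Nes and Prox1, named after their values were seen, were among these. EdU was given only 16 h before sampling, so reads of mature markers do not show that labelled cells had matured. Which cells these reads came from was not tested. Among neural stem cell markers, the fatty acid binding protein gene Fabp7 stood at 443 FPKM in Kmt2d +/mut and 194 in wild-type, Aldoc at 294 and 209.6, the glutamate transporter Slc1a3 at 186 and 134, and Thrsp at 65.8 and 303. Of 18 stem cell markers over the minimum, 6 were listed at 0 in wild-type and 4 in Kmt2d +/mut, and the authors' deposited table calls 0 of them. Among intermediate progenitor markers, the cyclin Ccnd2 stood at 219.9 FPKM in Kmt2d +/mut and 97.2 in wild-type, Hes6 at 154 and 75.8, Elavl2 at 51.1 and 138, and Igfbpl1 at 21.7 and 180.4. In that list the authors' deposited table calls Insm1, a transcription factor of neurogenic progenitors, higher (95.7 FPKM against a listed 0) and the antiproliferative gene Btg2 lower (a listed 0 against 75.2). The median log2 ratio was 0.08 for the stem cell list and 1.09 for the progenitor list, at percentiles 62.5 and 79.5 of matched random lists. For stem cell markers the mean of -0.28 had the other sign, and the 8 members above 0 in both libraries had a median of -1.06. Of 12 progenitor markers above 0 in both libraries, 7 were at least 2-fold higher and 3 at least 2-fold lower, with the median at percentile 91.5.

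Of the immature granule neuron markers, Dcx, which encodes the microtubule protein doublecortin, stood at 51.1 FPKM in Kmt2d +/mut and was listed at 0 in wild-type, and the authors' deposited table calls it higher. Nnat, the most abundant member, was nearly equal at 858 in Kmt2d +/mut and 886 in wild-type, and Ncam1 stood at 239.6 and 182. The neuropeptide gene Tac2 stood at 48.0 and 351, and Stmn2, a microtubule regulator of growing neurites, at 45.7 and 157. Of the mature granule neuron markers, the calcium buffer Calb1 stood at 178 FPKM in wild-type and was listed at 0 in Kmt2d +/mut, and the authors' deposited table calls it lower. The synaptic genes Snap25 and Gria2 stood at 539 and 369.6 in Kmt2d +/mut and at 685 and 479 in wild-type, while the calcineurin subunit Ppp3ca and the granule neuron gene C1ql2 stood at 243 and 193 in Kmt2d +/mut and at 148 and 161 in wild-type. The median was -0.57 for 19 immature markers and 0.37 for 21 mature markers, at percentiles 36.9 and 78.9, and for the mature markers the mean of -0.02 had the other sign. Over the 16 mature markers above 0 in both libraries, 6 were at least 2-fold higher and 1 lower, and the median was 0.81 at percentile 93.8. Over the 11 immature markers the authors tested, the median was -0.05.

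**Figure D2:**
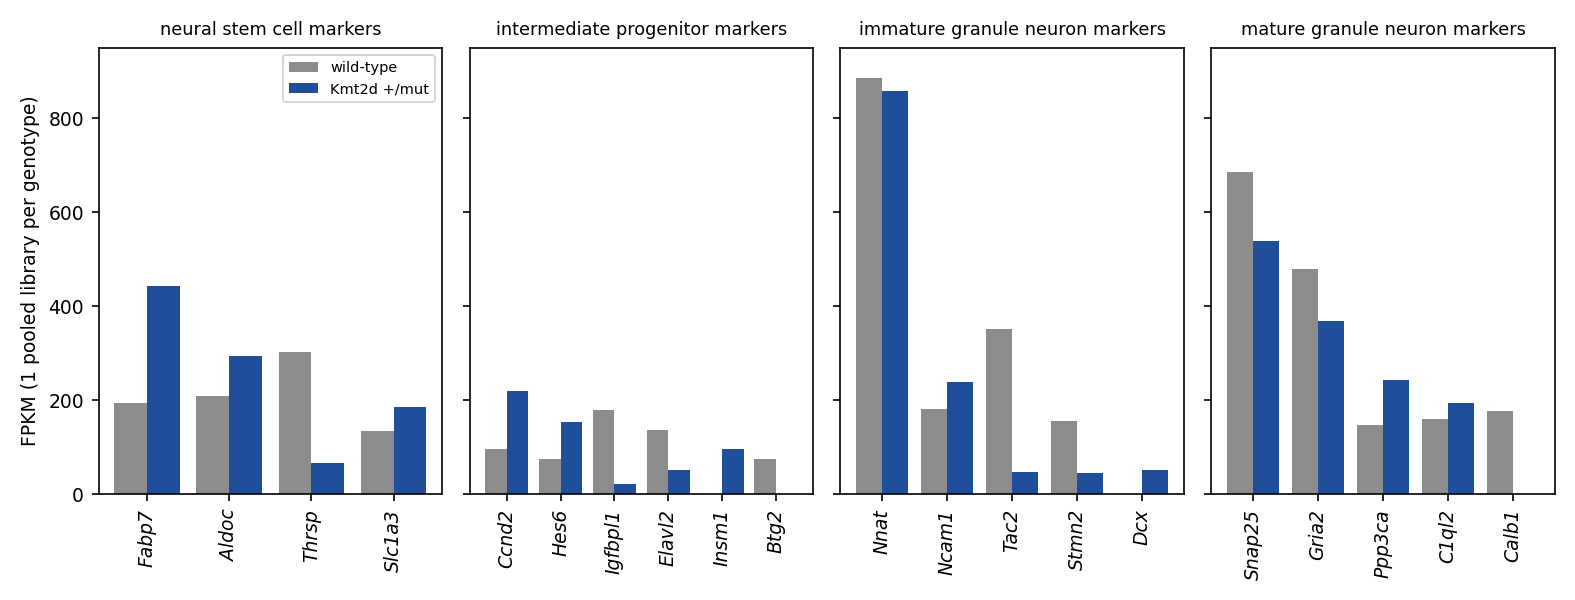
Bars give the FPKM, on a linear axis from 0, of the named marker genes of 4 stages of granule neuron formation in the wild-type (grey) and Kmt2d +/mut (blue) libraries, 1 pooled library per genotype with no error bars. Nnat stood at 886 and 858 FPKM, while Dcx and Insm1 were listed at 0 in wild-type and Btg2 and Calb1 in Kmt2d +/mut.

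Genes of DNA replication and the G1/S transition had the lowest median of the cell cycle lists. Orc1 and Gins4, parts of the machinery that starts DNA replication, and Ccne1, the cyclin of S phase entry, stood at 53.0, 198 and 136 FPKM in wild-type and were listed at 0 in Kmt2d +/mut, and the authors' deposited table calls all 3 lower. Tipin, a replication fork protein, stood at 349.6 FPKM in wild-type and 40.9 in Kmt2d +/mut. In the opposite direction, the histone mRNA binding protein gene Slbp stood at 169 in Kmt2d +/mut against a listed 0, which the authors' deposited table calls higher, and Orc6 stood at 184 in Kmt2d +/mut and 34.2 in wild-type. Of 58 members, 25 were listed at 0 in both libraries. Of 31 members over the minimum, 8 were listed at 0 in wild-type, 14 in Kmt2d +/mut and 9 in neither. Of the 31, 17 were at least 2-fold lower and 13 at least 2-fold higher. The list median of -3.07 lay at percentile 1.36 and was called apart, but came from this 2-sided spread. Over the 9 members above 0 in both libraries the median was 1.37, in the opposite direction. The list was no longer apart with a pseudocount of 0.1, at percentile 3.89, or among the 8 members the authors tested, at 9.19.

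Of the genes of G2/M and mitosis, the kinetochore kinase gene Ttk, the spindle checkpoint gene Mad2l1 and the spindle assembly factor Tpx2 stood at 203, 117 and 77.3 FPKM in Kmt2d +/mut and were listed at 0 in wild-type. The authors' deposited table calls these 3 higher and Sgol1, a protector of sister chromatid cohesion, lower, at 84.7 FPKM in wild-type and a listed 0. Of the 25 members over the minimum, 12 were listed at 0 in wild-type and 10 in Kmt2d +/mut. A further 32 members were listed at 0 in both libraries. Among genes of cell cycle exit, Fzr1, an activator of the anaphase-promoting complex, and the retinoblastoma gene Rb1 stood at 82.5 and 54.8 FPKM in Kmt2d +/mut against a listed 0, and the authors' deposited table calls both higher and Cdk5r1 lower, at a listed 0 against 64.2. Cdkn2d stood at 90.1 against a listed 0, Trp53 at 152 in Kmt2d +/mut and 20.1 in wild-type, and Gas1 at 84.3 and 12.3, with no call in the authors' deposited table. The median was 1.66 for G2/M and 3.14 for cell cycle exit, at percentiles 91.7 and 95.1. The G2/M list stood apart with a pseudocount of 0.1, a minimum of 5 or tested genes only, with medians of 4.501, 3.26 and 6.19. Over the 3 members above 0 in both libraries its median was 1.03 at percentile 74.7, and by the authors' fold 1.07 at 73.7.

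Hypoxia and glycolysis genes had medians above 0 that stayed within the range of random lists. Hif1a, the oxygen-regulated transcription factor, and its target Ldha stood at 76.2 and 135 FPKM in Kmt2d +/mut and were listed at 0 in wild-type, and the authors' deposited table calls both higher. The collagen-modifying enzyme genes P4ha2 and Plod1 stood at 102 and 136 FPKM in wild-type and were listed at 0 in Kmt2d +/mut, and the authors' deposited table calls both lower. Wsb1 stood at 515 in Kmt2d +/mut and 118 in wild-type, and Kdm3a at 42.5 and 119. Among glycolysis genes the authors' deposited table also calls Eno2 and Ldhb higher, at 81.8 and 208 FPKM against a listed 0, and none lower. Aldoa was nearly equal at 757 FPKM in Kmt2d +/mut and 714 in wild-type, Tpi1 stood at 511 and 223, and Pkm at 123 and 249. Of 15 glycolysis genes over the minimum, 7 were listed at 0 in wild-type and 1 in Kmt2d +/mut. Gapdh, which was chosen after its values were seen, is among the former with 34.2 FPKM in Kmt2d +/mut. The medians of 1.35 for hypoxia and 1.42 for glycolysis lay at percentiles 90.2 and 89.7, and over members above 0 in both libraries they were 0.54 and 0.48.

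Ribosomal protein genes were lower in Kmt2d +/mut as a list, and nuclear genes of oxidative phosphorylation ran both ways. Rpl35 stood at 278 FPKM in Kmt2d +/mut and 805 in wild-type, and Rps14 at 128 and 529.6. Rps4x and Rps9 stood at 504 and 670.4 in wild-type against a listed 0, and the authors' deposited table calls both lower and Rplp0 higher, at 253 in Kmt2d +/mut. Of 65 ribosomal protein genes over the minimum, 43 were above 0 in both libraries, of which 18 were at least 2-fold lower, 7 at least 2-fold higher and 18 within 2-fold. The list median of -1.25 lay at percentile 1.9 and was called apart, and over those 43 members it was -0.87 at percentile 0.83. With no minimum the percentile was 3.48, and among lists matched also on transcript length it was 6.42, so the list was apart in neither. Of 70 oxidative phosphorylation genes, 15 were listed at 0 in wild-type and 18 in Kmt2d +/mut. The authors' deposited table calls Atp5j2 and Cox6c higher, and those it calls lower include Cox6b1, Ndufa9 and Ndufb5, at 692, 444 and 307 FPKM in wild-type. Ndufa4 stood at 367 FPKM in Kmt2d +/mut and 1117 in wild-type, Uqcrh at 375 and 675, Atp5k at 849.7 and 642, and Ndufc2 at 509 and 369.7, and the list median of -0.77 lay at percentile 8.88 and was -0.21 over the 37 members above 0 in both libraries. The mitochondrially encoded list had 0 members in the table.

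Of 25 immediate early genes, which neurons switch on with activity, 9 were over the minimum and 16 were listed at 0 in both libraries. The authors' deposited table calls Dusp1 higher, at 81.5 FPKM against a listed 0, and Btg2, Homer1 and Nr4a2 lower, with Homer1 at 66.2 and Nr4a2 at 65.5 in wild-type. Their median of -4.56 lay at percentile 3.11, or -7.83 at 2.57 with a pseudocount of 0.1, and 8 of the 9 were listed at 0 in 1 library, while the only member above 0 in both, Klf6, named after its values were seen, had a log2 ratio of 3.51. Among heat shock and stress genes, the chaperone genes Hspa8, Hspa5 and Hsp90ab1 stood at 433, 394 and 625 FPKM in Kmt2d +/mut and at 403.5, 341 and 403 in wild-type, and Hsp90aa1 at 79.4 and 182. The stress transcription factor Xbp1 was listed at 0 in Kmt2d +/mut and stood at 139 in wild-type, which the authors' deposited table calls lower. The stress list had a median of 0.18 at percentile 65.9, and its mean of -0.99 had the other sign.

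Of 15 markers of oligodendrocyte precursors, another dividing cell type of the adult brain, all were over the minimum and 13 were above 0 in both libraries. Bcas1 stood at 254 FPKM in Kmt2d +/mut and 287 in wild-type, the growth factor receptor Pdgfra at 231 and 266, Olig1 at 198 and 293, and Neu4 at 338 and 189.6. The authors' deposited table calls Olig2 higher, at 77.8 against a listed 0, and Sox8 lower, at a listed 0 against 51.6. The list median of -0.17 lay at percentile 50.1, and its mean of 0.33 had the other sign. Of mature oligodendrocyte markers, the myelin gene Mbp stood at 162 FPKM in Kmt2d +/mut and 149 in wild-type, and Gjc3 at 172 and 117. The authors' deposited table calls Cldn11 and Trf higher, at 109.6 and 144 against a listed 0, and the list median of 0.66 lay at percentile 73.9.

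Astrocyte markers included Gja1 and Mlc1, at 53.6 and 179 FPKM in Kmt2d +/mut against a listed 0, both called higher in the authors' deposited table. Other leading members were close in both libraries, with the glutamate transporter Slc1a2 at 146 in Kmt2d +/mut and 105 in wild-type, and Ndrg2 at 64.6 and 75.5. The astrocyte median of 0.22 lay at percentile 60.9 and was -0.22 over the 7 members above 0 in both libraries. Of 7 microglia markers over the minimum, Ctss stood at 238 FPKM in Kmt2d +/mut and 372 in wild-type, Trem2 at 180.5 and 10.2, C1qa at 125 against a listed 0 and Fcer1g at a listed 0 against 279, with no call in the authors' deposited table. Their median of 2.07 lay at percentile 88.7, and over the 4 members above 0 in both libraries it was 3.05 and stood apart. Endothelial markers had 3 members over the minimum, of which the authors' deposited table calls Itm2a lower, at a listed 0 against 97.9 FPKM. Ramp2 stood at 267 in Kmt2d +/mut and 54.1 in wild-type, and the list median was -0.79 at percentile 39.4, or 0.75 over the 2 members above 0 in both libraries. Of mural cell and fibroblast markers only Tagln was over the minimum, at 103 FPKM in Kmt2d +/mut against a listed 0, and it stood at percentile 85.2.

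Interneuron and choroid plexus lists were called apart on very few genes. The choroid plexus list rested on Ttr, the transthyretin gene, at 382 FPKM in Kmt2d +/mut against a listed 0, which the authors' deposited table calls higher, and lay at percentile 98.2. The interneuron list rested on 4 genes with a median of 4.29 at percentile 97.6. Of these, the neuropeptide gene Sst stood at 313 and Dlx2 at 44.3 FPKM in Kmt2d +/mut against a listed 0, and Cck at 480 in Kmt2d +/mut and 55.7 in wild-type. The neuropeptide gene Npy went the other way, at 412 FPKM in wild-type and a listed 0 in Kmt2d +/mut, and the authors' deposited table calls it lower. With only tested genes or only genes above 0 in both libraries, the interneuron list held 3 members and 1 member and was not apart. Of the 22 lists, 4 were called apart, where 1.1 would be expected if the lists were independent random sets of genes. Some lists share members, so no excess over chance is read from this. The G1/S, ribosomal and interneuron lists each lost the call in at least 1 alternative. The choroid plexus list kept its call where it had a value, but this is no sign of stability in a list of 1 gene. It had no value by the authors' fold or above 0 in both libraries.

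**Figure D3:**
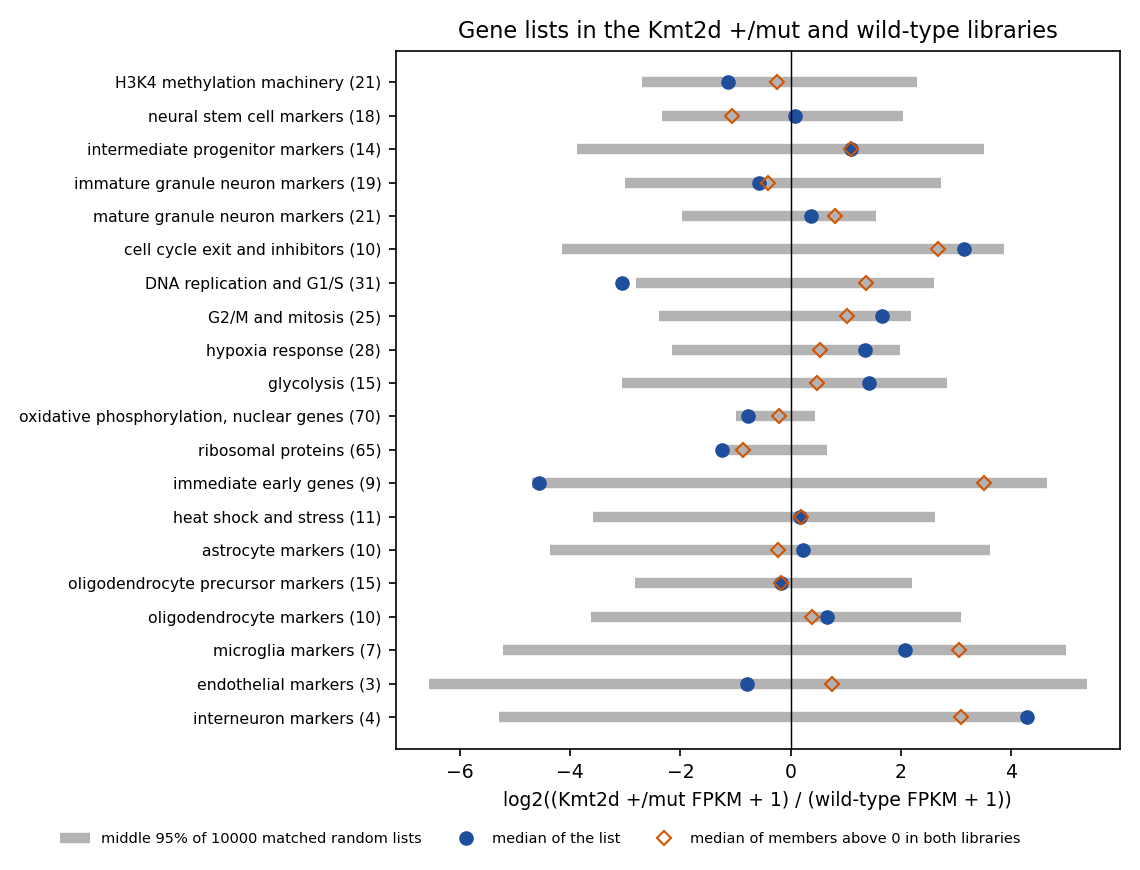
For each list with at least 3 genes over the minimum (number in parentheses), the blue point gives the median log2((Kmt2d +/mut FPKM + 1)/(wild-type FPKM + 1)), the grey bar the middle 95% of 10000 random lists matched on expression, and the open diamond the median of members above 0 in both libraries. DNA replication and G1/S lies below its bar at -3.07 while its diamond lies at 1.37, and ribosomal proteins lie below theirs at -1.25.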

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

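The result here was sought after the data were examined, and no explanation of it was tested. Among the 27 entries whose gene name had been turned into a date, which no comparison above used, 14 had an FPKM above 0 and the authors' deposited table calls 2. Both lie at the position of a septin gene, a family of cytoskeletal GTP-binding proteins. The entry over Sept10 (mm10, chromosome 10, 59141627 to 59221847) stood at 62.7 FPKM in Kmt2d +/mut and was listed at 0 in wild-type, with a q-value of 0.029 in the authors' deposited table. The entry over Sept3 (chromosome 15, 82274893 to 82294574) stood at 76.7 in wild-type and was listed at 0 in Kmt2d +/mut, with the same q-value in the authors' deposited table. With these entries that table's calls number 416 higher and 464 lower.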

How the results depend on the processing

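The restriction to genes above 0 in both libraries was chosen after the results were seen, and the other alternatives were planned. Of the values of list medians, counts and Kmt2d under an alternative, 176 kept their side of the threshold or stayed within 1.5 times (for Kmt2d, its counting interval), and 11 of these changed sign. The 11 belong to lists that were not apart in either setting: stem cell markers (-1.06 with a minimum of 5 and above 0 in both, -2.03 tested, -1.11 by the authors' fold), H3K4 machinery (1.89 tested), and, by the authors' fold and above 0 in both, immediate early genes (3.86 and 3.51), astrocytes (-0.23 and -0.22) and endothelium (0.73 and 0.75). Other moves of over 1.5 times that left a list not apart, beyond those given with the lists, included cell cycle exit (4.77, pseudocount of 0.1), oxidative phosphorylation (-0.47), stress (0.10), astrocytes (0.46), oligodendrocytes (1.10) and endothelium (-2.17) among tested genes, and H3K4 machinery (-0.24) and oligodendrocytes (0.38) above 0 in both. By the authors' fold they also included H3K4 machinery (-0.24), mature granule neurons (0.82), hypoxia (0.56), glycolysis (0.49), oxidative phosphorylation (-0.21) and oligodendrocytes (0.39). With a minimum of 5, mature granule neurons gave 0.81. The 170 values of single named genes say nothing of stability, since these genes were named for extreme ratios whose sign these alternatives cannot turn. With a pseudocount of 0.1, the G1/S median was -3.58 and no longer apart and the G2/M median was 4.501 and apart. With no minimum the ribosomal median was -1.11 and no longer apart. With a minimum of 5, G2/M (3.26) and mural cell markers (6.69, set by the level of Tagln alone and the pseudocount) were apart. Among tested genes only, 1250 genes were at least 2-fold higher and 1369 lower, since fewer genes enter. There the G1/S median was -3.78 and the interneuron median 3.08, neither apart, and G2/M was apart at 6.19. With the authors' own fold the G1/S median reversed to 1.45, microglia were apart at 3.14 and interneurons, at 3.11, were not. Among genes above 0 in both libraries, which leaves fewer genes, 1001 were higher and 975 lower, G1/S reversed to 1.37, microglia were apart at 3.05 and interneurons, at 3.08, were not. Both G1/S reversals came from leaving out the 22 G1/S members listed at 0 in 1 library, and the cause of the other differences was not tested. At a q-value under 0.01 the authors' deposited table calls 31 genes higher and 28 lower, and with an FPKM of 1 or more in both libraries 0 and 0. Centring moved all ratios by 0.02, and keeping symbols with 1 entry moved nothing, as every symbol had 1. Kmt2d gave no value among tested genes. No paired analysis was possible because there is 1 library per genotype. By the estimated fragment counts, 11.2% of single-transcript genes above 0 in wild-type and 13.5% in Kmt2d +/mut rested on about 1 fragment.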

Other observations

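The test of transcript length was set before its result was seen, and the other tests in this part, with the choice of the X- and Y-linked genes below, were made after the results were seen. Xist, the RNA that silences an X chromosome, stood at 433 FPKM in wild-type and 299 in Kmt2d +/mut, and its antisense partner Tsix at 519 and 403. Reads of these overlapping genes cannot be told apart without strand. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 in both libraries.

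The share of genes listed at 0 in the other library became smaller with the level in the library where the gene was higher. It was 85.8% for genes at 1 to 10 FPKM, 61.9% at 10 to 50, 50.5% at 50 to 100, 43.1% at 100 to 200, 36.0% at 200 to 500 and 17.4% at 500 or more.

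All 878 genes called in the authors' deposited table were listed at 0 in 1 library. Unequal depth could not be decided by the value of 1 fragment, which was 1.01 times as large in Kmt2d +/mut as in wild-type. Both values came from the same narrow window, so a large difference could not have appeared. Steps fitted separately, over a limited range, were 4.58 in wild-type and 4.68 in Kmt2d +/mut. At equal depth, counting error of sequenced fragments is argued against. Of 307 single-transcript genes with 10 or more estimated fragments in 1 library, 187 were listed at 0 in the other, where Poisson counting gives 0.0346. Many fragments can be copies of few molecules, so counting error of the molecules captured before amplification could not be decided. Genotype as the whole cause is argued against by 10.8% of ribosomal protein genes being listed at 0 in wild-type, if such genes are taken to be expressed there. Loss of transcripts before sequencing stays open: 33.8% of ribosomal protein genes were listed at 0 in 1 library, but so were 59.7% of all genes over the minimum, and shared reads or failed estimates could give the same. Genotype as part of the cause cannot be told apart from differences between pools with 1 library per genotype.

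In the authors' deposited table none of the tested genes above 0 in both libraries is called. Whether these genes differ less could not be decided, since genes listed at 0 have no fold to set beside theirs. Of the 1826, 264 differ by 16-fold or more, 128 of them higher in Kmt2d +/mut. The smallest q-value of the 264 in the authors' deposited table is 0.178. A candidate explanation is that the authors' test treats a gene with no fragments in 1 library differently, and the settings needed to check this are not given in the sources used here. No biological explanation of this pattern was tested.

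Ribosomal protein genes had a median log2 ratio of -1.25, under the bound of -1.16 that holds the lowest 2.5% of matched lists. Genes listed at 0 are argued against as the source, since over members above 0 in both libraries the list lay at percentile 0.83. Transcript length may contribute: among lists matched on 5 bins of level and 5 of length the bound was -1.50 and the list lay at percentile 6.42, while the same 5 bins of level alone gave -1.20 and 2.2. The call ended because the bound moved, with the list median the same. The median of the random lists moved less, from -0.20 with level alone to -0.33 with length added. Part of the bound's move was therefore a wider spread of the random lists. Reads shared with pseudogenes were not tested, and an effect of genotype stays open with 1 library per genotype.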
